A study of Mus musculus with 21 samples.

How the data were processed

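Expression was measured in 21 mouse samples on Illumina bead arrays of 24613 probes. Per the labels these were interphase zygotes (3 arrays), mitotic zygotes (3), 2-cell embryos (2), ES cells (2), genomeless embryos (2), interphase transfer embryos (2), M phase transfer embryos (4) and drug controls (3), with embryos cultured in KSOM and pooled in groups of 20. RNA was isolated with PicoPure, amplified with the Illumina total prep kit and labelled with biotin. The submitters' processing notes name GenomeStudio, with no version. The deposited non-normalised values are probe signal, an intensity after background subtraction and without normalisation between arrays. Beside each signal the authors deposited a detection p-value for that probe against background. The deposited processed values are the same intensity times 1 factor per array, so that all arrays have a mean of 198.09. Which donor cell gave the transferred genomes and what tool settings were used are not given in the sources used here. ES cell A has a source label that names peripheral blood, and it was kept as an ES cell sample on its title and the markers checked.

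Depth differed between arrays. Mean signal and the number of probes with a detection p below 0.01 were 122.15 to 166.43 and 6933 to 7787 in interphase zygotes, 123.85 to 174.47 and 7887 to 8131 in mitotic zygotes, 96.85 to 117.87 and 7259 to 7267 in 2-cell embryos, 107.23 to 124.51 and 6442 to 6849 in drug controls and 151.37 to 175.91 and 6711 to 8317 in ES cells. In M phase transfer embryos they were 73.0 to 687.57 and 5555 to 7531, in interphase transfer embryos 12.79 to 535.14 and 3412 to 5816 and in genomeless embryos 11.25 to 334.78 and 2426 to 4816. The median over genes of the SD within a group was 0.103 in mitotic zygotes, 0.166 in 2-cell embryos, 0.197 in drug controls, 0.277 in interphase zygotes, 0.285 in ES cells, 0.4 in M phase transfer, 0.505 in genomeless and 0.511 in interphase transfer embryos.

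Signals were background-corrected with the normexp model (offset 50), quantile-normalised and log2-transformed with limma 3.58.1 in R 4.3.3. The design, fixed before the data were examined, named neqc (offset 16), which estimates background from detection p-values, as the main method. It named the route used here as the fallback for values already background-subtracted, as the deposited ones are. Probes with a detection p below 0.01 on at least 2 arrays were kept (11541). Of all probes, 20984 carried 1 gene symbol, 1 carried several and 3628 none, and the probe with the highest mean was taken for each gene, which gave 8527 genes, 1377 of them with more than 1 probe kept. After the data were examined, mitotic arrays A and C and drug control arrays B and C, with an SD of log2 differences under a limit of 0.2, were averaged as repeat hybridisations, although the design had named all 21 arrays as separate samples. Treating the 21 as separate is 1 of the alternatives.

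A linear model with a mean per group was fitted to the 19 samples with limma, with moderated variances (11 residual degrees of freedom), and 11 comparisons chosen before the data were examined were tested with Benjamini-Hochberg adjustment within each. Genes with an adjusted p below 0.05 were called. The 19 gene lists were fixed from general knowledge before the data were examined, and the 18 with at least 5 tested members went through camera in limma (preset correlation 0.01, and again with an estimated correlation), adjusted over the lists within each comparison (198 tests in all). A further 3 lists were derived from the samples (adjusted p below 0.05 and a log2 difference of at least 1) and had 15 tests of their own, adjusted together. Where a chip holds both groups, values with chip as a block and within chips are given beside the called lists. M phase transfer, interphase transfer and genomeless samples were split evenly over chips 5 and 6. Among these groups the block therefore cannot change a median and is no check. Replicate letters were checked for pairing (mean correlation of residuals 0.01 over 57 same-letter pairs and 0.12 over 20 same-chip pairs) and not used as pairs. Interphase transfer and genomeless samples of the same letter, which also share a chip, correlated at 0.46. No comparison has at least 3 samples on each side, so no test on other splits of the samples was run.

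Genes named in the report are the 6 largest called differences in each direction that were detected on every array of the brighter group, up to 4 members of each list with the largest absolute difference, and a set chosen in advance (Smarca4, Pou5f1, Nanog, Sox2, Klf4, Zfp352, Eif1a and others). Some were passed over because their probes differed in direction or another probe of the gene was detected in the dimmer group, and 2 that met these rules are not reported here. Of the set chosen in advance, Zscan4c, Zscan4d, Zscan4f, Hspa1a and Hspa1b had no tested probe. The alternatives set in advance changed background correction, scaling, filter, chip and replicate blocks, variance moderation and the fitting of groups alone, and left out each replicate. Alternatives added after the data were examined were 21 separate arrays and neqc background (offset 16), both named in the design for the main fit, leaving out the 2 dim arrays, and array quality weights. Leaving out the dim arrays leaves a single genomeless and a single interphase transfer sample. The model and list tests, but not normalisation, filtering or probe choice, were run on simulated log2 values. In each comparison 100 genes were changed by a log2 of 1 and 100 by 2. Over a pooled and a group-specific spread, 22 of 22 raised lists and 0 unchanged lists had a camera p below 0.05. Genes were independent there and every member of a raised list was raised, so this says little about correlated lists. With the group-specific spread, false calls were 171 for interphase transfer against genomeless, 118 for M phase against interphase transfer, 112 for M phase transfer against genomeless, 16 for drug control against genomeless, and 4 or fewer elsewhere.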

Results

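Gene expression was measured in mouse preimplantation embryos and embryonic stem (ES) cells on Illumina bead arrays with 24613 probes. The 21 arrays formed 8 groups on 6 chips, and each embryo array was made from 20 pooled embryos. There were 3 arrays of interphase zygotes (24 to 28 h after hCG), 3 of zygotes held in mitosis with nocodazole (32 to 34 h), 2 of 2-cell embryos (48 to 50 h) and 2 of ES cells. At the age of the 2-cell embryos there were 3 arrays of drug controls, which had been exposed to nocodazole at mitosis, and 2 of genomeless embryos, whose genome had been removed and not replaced. Nuclear transfer embryos of the same age made up 2 arrays for interphase recipients and 4 for M phase recipients, and the donor cell of these transfers is not given in the sources used here. Genomeless and M phase transfer embryos were taken 22 to 24 h after enucleation or transfer, and this time is not given for interphase transfer. Recipient stage can therefore not be told apart from time since transfer or donor cell. Mitotic arrays A and C, and drug control arrays B and C, were as alike as repeat hybridisations of the same RNA (SD of their log2 differences 0.128 and 0.109, against 0.38 to 1.309 for the other 17 pairs within a group). Each of these pairs was averaged and counted once, a choice made after the data were examined, which leaves 19 samples and n = 2 in most groups.

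On the main axis of variation, transfer embryos of M phase recipients lay with 2-cell embryos and those of interphase recipients with zygotes. The first principal component held 43.2% of the variance and put all interphase zygotes, mitotic zygotes, genomeless embryos and interphase transfer embryos between -69.5 and -51.6. All 2-cell embryos, drug controls, M phase transfer embryos and ES cells lay between 49.5 and 62.8. The second component (16.7%) set genomeless and interphase transfer embryos (-101.2 to -26.3) apart from zygotes (36.5 to 51.3), and the third (10.8%) set ES cells (-88.4 and -74.8) apart from all other samples (-12.4 to 27). M phase transfer embryos correlated with 2-cell embryos (mean r = 0.894) and drug controls (0.898) about as well as with each other (0.889). The last value is lowered by a split between chips. Over probes, M phase transfer arrays correlated at 0.976 and 0.9 within chips and at 0.843 to 0.889 across them. The 2-cell samples correlated with each other at 0.961 and drug controls at 0.952. Interphase transfer embryos were closer to mitotic zygotes (0.704) and genomeless embryos (0.71, from 0.612 to 0.908) than to 2-cell embryos (0.514). They correlated with each other at only 0.674. Of the genes raised at least 2-fold between mitotic zygotes and 2-cell embryos, among them the cell-surface gene Timd2 and the phosphatase gene Ppp2cb, the arrays of M phase transfer embryos detected 93.4% on average, those of interphase transfer embryos 30.6% and those of genomeless embryos 22.9%. The shares in interphase transfer and genomeless embryos lie below the 49.5% of interphase and 56.2% of mitotic zygotes. Their arrays also detected fewer genes in all (1896 to 4510, against 5198 to 6071 in zygotes). Genomeless array B (mean signal 11.25) and interphase transfer array B (12.79) were far dimmer than all others (73.0 to 687.57), and p-values here measure only the spread between samples, which may be technical. The bar chart of called genes gives their number and direction in each of the 11 comparisons.

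**Figure D1:**
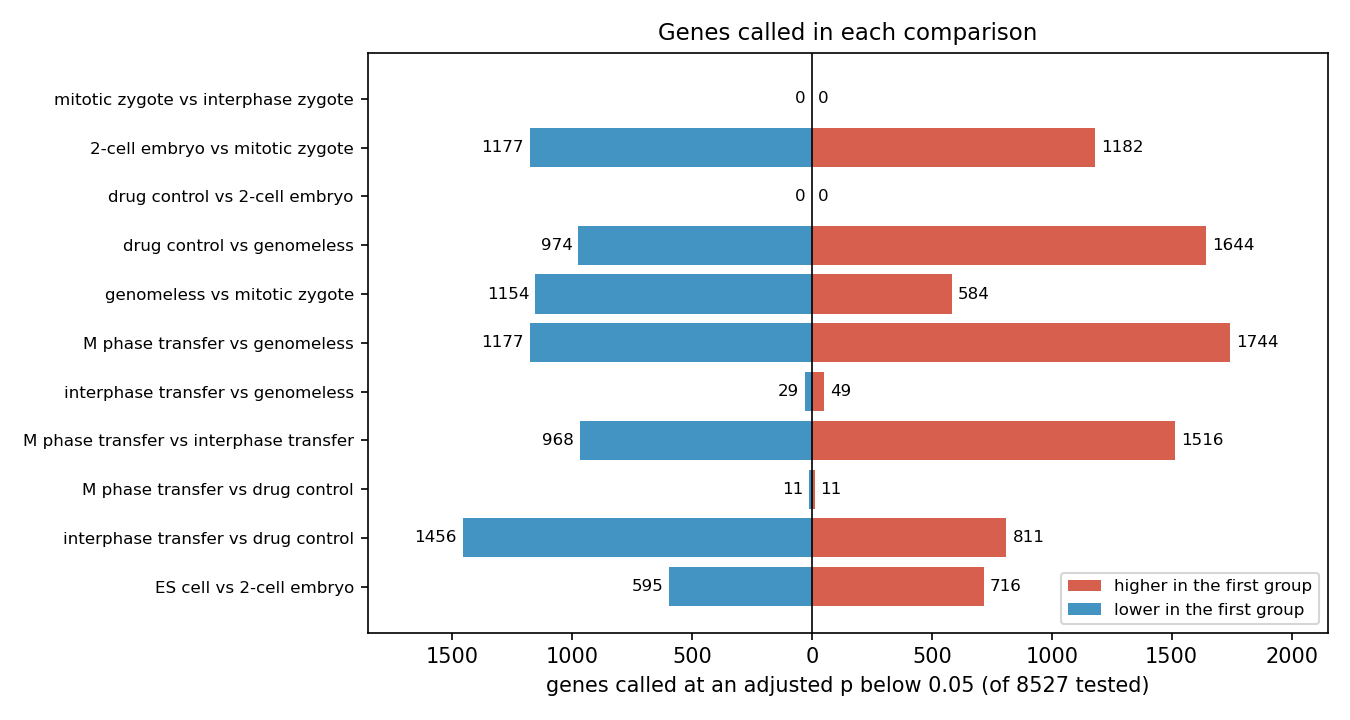
Number of genes called by limma at an adjusted p below 0.05 in each comparison (horizontal axis, genes of 8527 tested), with genes higher in the first-named group as red bars to the right of 0 and lower ones as blue bars to the left. M phase transfer against drug controls gave 11 higher and 11 lower, while interphase transfer against drug controls gave 811 and 1456.

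The step from mitotic zygote to 2-cell embryo (n = 2 against 2) exchanged oocyte transcripts for those of the embryonic genome. Timd2, a cell-surface receptor gene, rose by a log2 difference of 6.57 ± 0.61 (SE; adjusted p = 5.79e-06), Guca1a, which encodes a guanylate cyclase activator, by 6.47 ± 0.62 (7.07e-06), and the ribosomal protein gene Rps3 by 6.01 ± 0.69 (2.81e-05). Ppp2cb, a catalytic subunit of protein phosphatase 2A, rose at least 69.3-fold (3.76e-07), the tetraspanin Cd63 at least 66.2-fold (0.000427) and the endosomal adaptor Pheta1 at least 54-fold (0.000347). A value of at least N-fold is given where the tested probe was above background on no array of the dimmer group, and it takes as the level there, on each array, the lowest signal of any detected probe or the probe's own value if higher. Where the dimmer group was detected on part of its arrays the difference is given as measured, as for Timd2. With undetected arrays at their floor these 79 differences lie closer to 0 by a median of 0.65 and at most 1.51, and 22 of them by at least 1. The oocyte growth factor Bmp15 fell (-5.21 ± 0.47, 4.91e-06), as did the gap junction gene Gja4, which links oocyte and granulosa cells (-5.08 ± 0.49, 7.07e-06), and the PRAME family gene Pramel34 (-5.10 ± 0.35, 6.94e-07). Falls of the same order were measured for Oas1c (-5.32 ± 0.63, 3.77e-05), the thiol reductase Glrx (-5.15 ± 0.60, 3.32e-05) and the germline helicase Tdrd12 (-5.58 ± 1.01, 0.00101). Of 8527 genes, 2359 were called, 1182 higher and 1177 lower.

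Protein synthesis genes rose together at this step. Of 54 genes named as ribosomal proteins, 3 of which are S6 kinases, 32 were called higher and none lower (36 higher and 2 lower adjusted over the list alone), as for Rps27 (5.66 ± 0.87, 0.000325) and Rpl13 (5.47 ± 0.60, 1.96e-05). The ribosomal protein median was 2.42 (2.32 with bounded genes at their bound; list adjusted p = 1.34e-12, adjusted p = 0.0537 with an estimated correlation). Ribosome biogenesis genes had 20 of 36 called higher and none lower (25 and 0 adjusted over the list alone), with a median of 1.89 (1.84 with bounds; 7.19e-09). They were led by the processing factor Rrp12 (4.38 ± 0.40, 5.43e-06), the RNA polymerase I subunit Polr1e (4.09 ± 0.51, 5.68e-05) and nucleolin, Ncl (at least 15.2-fold, 7.87e-06). The oxidative phosphorylation list had 18 of 64 higher and 3 lower (20 and 3 adjusted over the list alone; median 0.91, 0.85 with bounds, 0.00122, adjusted p = 0.472 with an estimated correlation), and it held both Cox7c (at least 17.7-fold higher, 0.000985) and Cox6a2 (-4.56 ± 0.90, 0.00186). Proteasome genes had 9 of 31 higher and 2 lower (11 and 2 adjusted over the list alone; median 0.67, 0.67 with bounds, 0.0289, adjusted p = 0.153 with an estimated correlation), with Psmb5, a catalytic subunit, up by 4.19 ± 0.34 (2.36e-06). Splicing genes had 10 of 38 higher and 1 lower (10 and 1 adjusted over the list alone; median 0.54, 0.42 with bounds, 0.041, adjusted p = 0.161 with an estimated correlation), with the core spliceosome genes Snrpd2 (4.8 ± 0.81, 0.000597) and Snrpb (4.61 ± 0.69, 0.000265) at the top.

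Oocyte genes were lost and only part of the 2-cell list was gained. The oocyte list had 27 of 40 genes lower and none higher (0 higher and 31 lower adjusted over the list alone), with a median of -2.26 (-2.21 with bounds; 2.29e-11), including Nlrp9c (-4.65 ± 0.50, 1.57e-05) and Zar1, which is needed for the first cleavages (-4.59 ± 0.86, 0.00128). Among 13 genes known for activation at the 2-cell stage, 6 rose and 2 fell (9 and 2 adjusted over the list alone; median 1.46, 1.40 with bounds, 0.00659, adjusted p = 0.153 with an estimated correlation). Pramel7 rose at least 41.3-fold (4.97e-08), Obox6 at least 14.6-fold (0.000188), Tdpoz1 at least 12.5-fold (0.00371) and the translation factor Eif1a at least 4.54-fold (0.00142), while Zfp352 was not called (0.56 ± 0.55, 0.513). Of the pluripotency regulators, Klf5 (4.87 ± 0.47, 7.87e-06), Dppa4 (4.6 ± 0.64, 0.000145) and Klf2 (4.18 ± 0.36, 3.62e-06) rose most, and Nanog rose at least 3.03-fold (0.0134). Klf4 was called at 1.39 ± 0.48 (0.0427), but not with a chip block, in the mean-scaled values or without any 1 of the samples, and the Nanog call was likewise lost without any 1 sample. Pou5f1 (-1.23 ± 0.76, 0.263) and the chromatin remodeller Smarca4 (1.61 ± 0.65, 0.0793) were not called. The G1 cyclin Ccne1 rose by 5.56 ± 0.65 (3.32e-05) and the checkpoint gene Bub3 fell (-3.95 ± 0.53, 0.000103), and the pluripotency (median 0.23), DNA replication (0.10), M phase (-0.06) and chromatin (-0.06) lists were not called.

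The same change was measured within chip 4, which held both 2-cell arrays and mitotic arrays B and C. There the ribosomal protein median was 2.41, that of ribosome biogenesis genes such as Rrp12 1.89, oxidative phosphorylation 0.88, proteasome 0.66, splicing 0.56, oocyte genes -2.24 and the 2-cell list 1.49. With chip as a block the medians were 2.41, 1.9, 0.88, 0.66, 0.55, -2.24 and 1.49, and 2932 genes were called (1392 higher, 1540 lower). The count of 2359 was 1326 without mitotic sample A and C, 1341 without mitotic B, 1452 without 2-cell A and 1399 without 2-cell B. Of the called genes 50.1% were higher, against 38.9% in the deposited mean-scaled values, where the median of all genes moved from -0.02 to -0.20. Genes that changed at least 2-fold at this step, 1127 called higher and 1099 called lower, served below as lists of activated and maternally lost genes. They were chosen on these samples, so their direction in this comparison is no separate evidence. The dot plot of gene levels shows Timd2, Ppp2cb and Bmp15 in every sample.

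**Figure D2:**
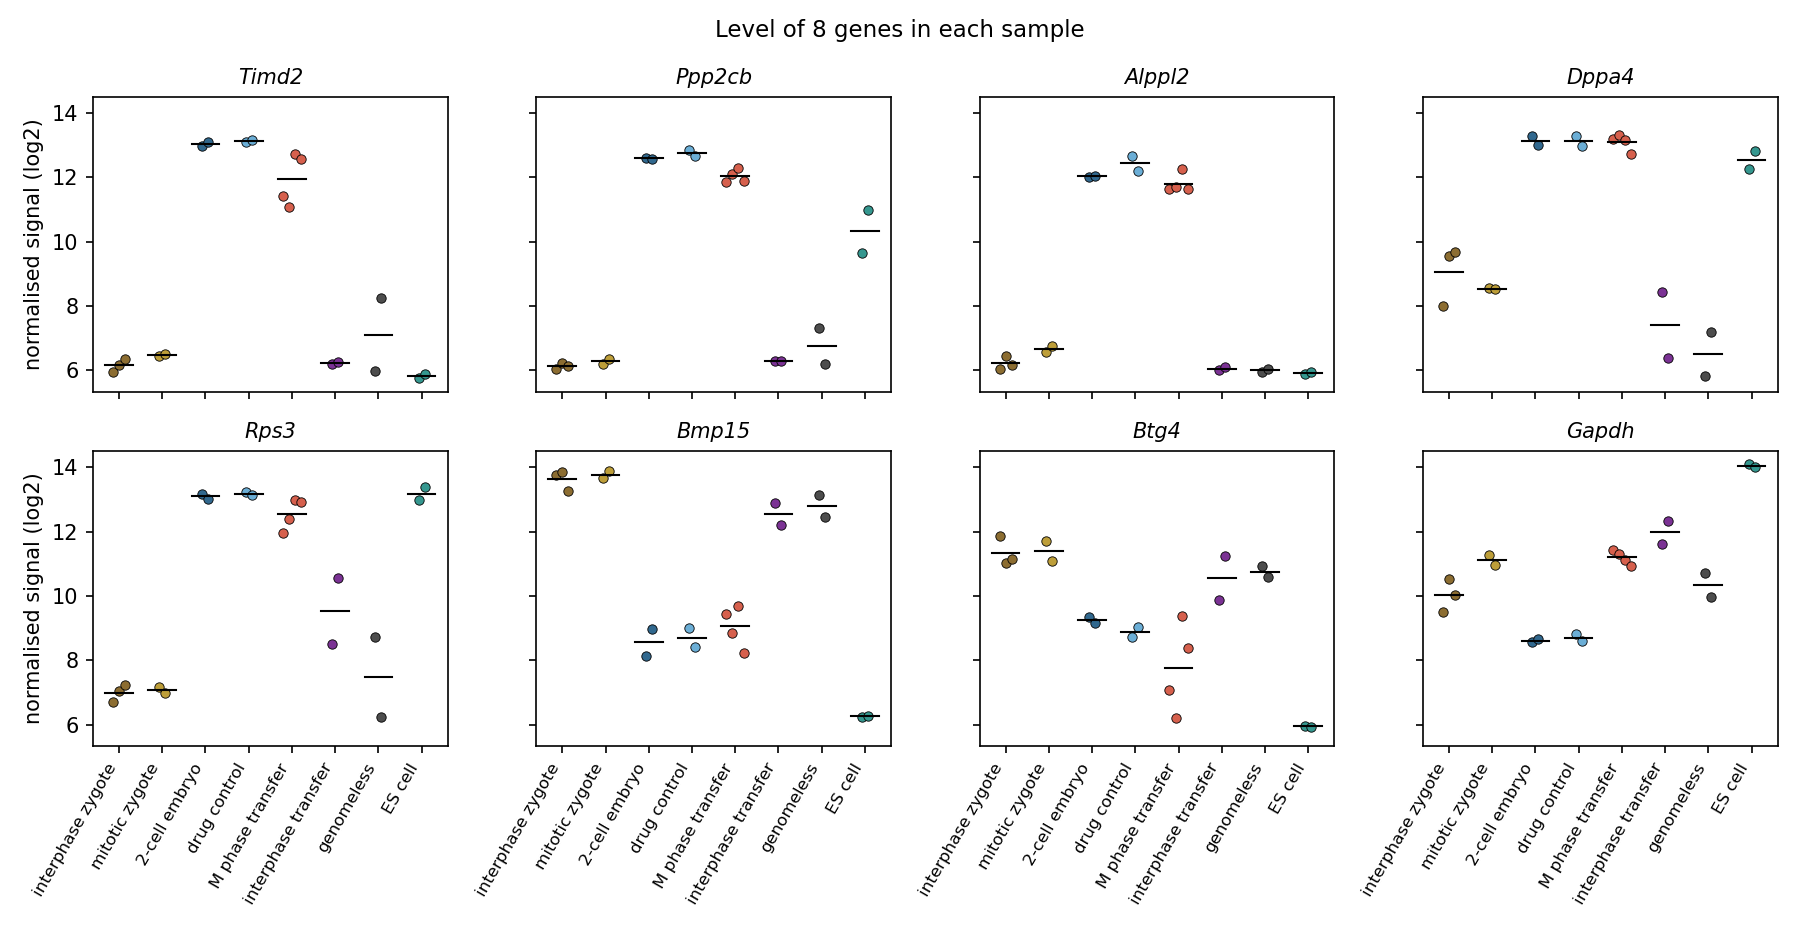
Normalised signal (vertical axis, log2) of Timd2, Ppp2cb, Alppl2, Dppa4, Rps3, Bmp15, Btg4 and Gapdh in each of the 19 samples, with points as samples (repeat hybridisations averaged) and lines as group means. Timd2, Ppp2cb and Alppl2 are high in 2-cell, drug control and M phase transfer embryos and near background in zygotes and interphase transfer embryos, while Bmp15 runs the other way.

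Zygotes at interphase and in mitosis (n = 3 against 2) were not told apart gene by gene in the model used. The largest difference within the oocyte list was in the homeobox gene Obox5, 2.69 ± 0.53 higher in mitosis (adjusted p = 0.301), the only gene of that list called when adjusted over the list alone. The replication origin gene Orc6 (2.33 ± 0.63, 0.527) and the ribosomal protein gene Rpl13 (-2.20 ± 0.55, 0.436) were not called. limma called 0 genes, with 403 below an unadjusted p of 0.05, a median SE of 0.47, and 0 called with chip as a random block, as a fixed chip term cannot be separated from group here. Without interphase sample A 10 genes were called, with 21 separate arrays 25 and with array quality weights 1273. No list was called (lowest ribosomal protein genes, -0.24, 0.0811). On simulated data with the spread of these groups, 42% of genes changed by a log2 of 2 and 1% of those changed by 1 were recovered.

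No gene was called between drug controls (n = 2), which had passed through nocodazole, and 2-cell embryos (n = 2). The proteasome ATPase gene Psmc1 (-2.14 ± 0.65, adjusted p = 1), the maternal-effect gene Nlrp5 (1.11 ± 0.59, 1) and Nanog (0.54 ± 0.58, 1) were not called. limma called 0 genes, with 96 below an unadjusted p of 0.05, 0 with chip as a fixed or random block, and 1 without drug control A. The lowest list value was for oxidative phosphorylation (-0.15, 0.226; -0.19 with a chip block, 0.17 within chip 4, the shared chip), and activated genes stood at a median of 2.35 (SD 0.04) over mitotic zygotes in drug controls and 2.38 (SD 0.04) in 2-cell embryos. In simulated data only 20% of genes changed by a log2 of 2 and 0% of those changed by 1 were recovered. Drug effects of this size on single genes are therefore not excluded.

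Embryos without a genome lost part of their maternal RNA but did not gain the 2-cell programme. Against mitotic zygotes (n = 2 against 2), transcripts fell for the midzone protein Prc1 (-5.79 ± 0.91, -4.48 with the undetected array at its floor, adjusted p = 0.000904), the tubulin Tubb4b (-5.33 ± 0.66, -4.09 with the floor, 0.000206), the complex III subunit Uqcrc2 (-5.02 ± 0.39, -3.74 with the floor, 1.07e-05) and the mitotic kinase Aurka (at least 12.6-fold, 8.38e-07). Glrx fell at least 12.5-fold (0.000117), the acetyltransferase gene Elp3 at least 10.2-fold (0.000514) and F8a at least 9.97-fold (0.000332). Among oocyte genes Rfpl4 (-3.75 ± 0.78, 0.00466), Oas1d (-3.00 ± 0.62, 0.00455) and Zar1 (-2.73 ± 0.86, 0.0364) fell, though Zar1 was not called with a chip block. Others were measured higher, namely the calcium-binding S100a6 (at least 41.5-fold, 0.0178), the keratin Krt17 (at least 15.7-fold, 0.00478), Dhrs7 (at least 12.2-fold, 0.0122), the kinase gene Pik3cb (4.22 ± 0.78, 0.00236) and Rmnd5a (4.20 ± 0.47, 0.000117). Activated genes stayed at a median of -0.04 (SD 0.05) relative to mitotic zygotes and lost genes reached -1.42 (SD 0.30), against -2.25 (SD 0.03) in 2-cell embryos.

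Lists of cell division, oocyte, protein turnover, ribosome biogenesis and energy genes were called lower in genomeless embryos, and none of these calls held with an estimated correlation. DNA replication genes had 1 of 38 higher and 16 lower (1 and 16 adjusted over the list alone), with the helicase gene Mcm5 down at least 7.94-fold (4.09e-05). The DNA replication median was -1.36 (-0.46 with bounds, -1.42 with a chip block; adjusted p = 0.000166, adjusted p = 0.0789 with an estimated correlation). M phase genes had 1 of 29 higher and 13 lower (1 and 14 adjusted over the list alone), with the meiotic kinase gene Aurkc at -3.76 ± 0.63 (0.0013). The M phase median was -1.34 (-0.38 with bounds, -1.49 with a chip block; adjusted p = 0.000161, adjusted p = 0.103 with an estimated correlation). Oocyte genes had 0 of 40 higher and 15 lower (0 and 20 adjusted over the list alone). The oocyte median was -0.98 (-0.8 with bounds, -1.14 with a chip block; adjusted p = 0.000166, adjusted p = 0.188 with an estimated correlation). Proteasome genes had 1 of 31 higher and 11 lower (1 and 11 adjusted over the list alone), with Psmc5 at -3.50 ± 0.49 (0.000454). The proteasome median was -1.11 (-0.57 with bounds, -1.03 with a chip block; adjusted p = 0.00337, adjusted p = 0.103 with an estimated correlation). Ribosome biogenesis genes had 0 of 36 higher and 10 lower (0 and 11 adjusted over the list alone), with Brix1 at -4.55 ± 1.21 (-3.05 with the floor, 0.017). The ribosome biogenesis median was -0.5 (0 with bounds, -0.6 with a chip block; adjusted p = 0.0216, adjusted p = 0.271 with an estimated correlation). Oxidative phosphorylation genes had 2 of 64 higher and 13 lower (2 and 14 adjusted over the list alone). The oxidative phosphorylation median was -0.75 (0 with bounds, -0.57 with a chip block; adjusted p = 0.0424, adjusted p = 0.692 with an estimated correlation, and 0.26 with the block, which ended the call).

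No chip held both genomeless embryos and mitotic zygotes, so chip enters only as a block. Of 1738 genes called by limma, 584 were higher and 1154 lower (2667 with the block, 1068 and 1599). The count was 625 without mitotic A and C, 653 without mitotic B, 2771 without genomeless A and 1144 without genomeless B. Genes higher in genomeless embryos, S100a6 among them, depend on the scaling. They made up 33.6% of those called, but 4.3% with median scaling and 14.9% in the mean-scaled values, where the median of all genes moved from -0.10 to -0.36 and -0.43, and 47.2% (878 of 1860) without the 2 dim arrays. The 3 tested genes of the cumulus and granulosa list had a median of 1.18, and of 0.27 with median scaling.

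Compared with drug controls of the same age, genomeless embryos had less of most activated transcripts and of some that zygotes already held. Prc1 was among the latter, with a mean of 12.74 in mitotic zygotes and a fall in genomeless embryos. Drug controls (n = 2 against 2) held at least 34.8-fold more Dppa4, a chromatin protein of pluripotent cells (adjusted p = 5.84e-06), at least 34.6-fold more Timd2 (8.93e-06), at least 21.5-fold more of the alkaline phosphatase transcript Alppl2 (1.14e-08) and at least 19.2-fold more Ccne1 (2.36e-05). The serine synthesis gene Psat1 was at least 15.9-fold (3.26e-07), Mad2l1bp at least 16.6-fold (5.77e-07) and Pramel7 at least 15-fold (4.24e-08) higher. Rps3 (5.70 ± 0.69, 3.56e-05), Prc1 (5.10 ± 0.91, 0.000781), Nanog (at least 1.51-fold, 0.00273) and Eif1a (at least 1.76-fold, 0.0013) were also higher, while Pou5f1 (adjusted p = 0.338), Klf4 (0.226) and Smarca4 (0.192) were not called. Genomeless embryos had more Tshz1 (-5.46 ± 1, 0.000996), Efna5 (-4.97 ± 0.71, 0.000148), the p53 regulator Mdm4 (-4.85 ± 0.57, 2.81e-05), Bmp15 (-4.08 ± 0.47, 2.44e-05), the cytoplasmic polyadenylation factor Cpeb1 (-3.77 ± 0.54, 0.000157) and Rims1 (at least 17-fold lower in drug controls, 5.63e-05). Of 1127 activated genes 902 were higher and 6 lower in drug controls (median 2.39, 1.25 with bounds, 1.9e-73, adjusted p = 1.48e-08 with an estimated correlation). Of 1099 lost genes 29 were higher and 318 lower (median -0.67, -0.40 with bounds, 4.56e-14, adjusted p = 0.012 with an estimated correlation).

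Nearly every list of growth genes differed. The DNA replication and M phase lists had not been called from mitotic zygote to 2-cell embryo (0.1 and -0.06) but were lower in genomeless embryos than in mitotic zygotes (-1.36 and -1.34). For them, loss of RNA held by zygotes and missing new RNA are not separated. Ribosome biogenesis genes had 30 of 36 higher and 0 lower (32 and 0 adjusted over the list alone), led by Ebna1bp2 (6.11 ± 0.54, 2.8e-06) and Pno1 (5.29 ± 0.57, 1.31e-05). The ribosome biogenesis median was 2.86 (1.78 with bounds, 3.11 with a chip block, 3.19 within chip 6; adjusted p = 5.37e-14). Proteasome genes had 17 of 31 higher and 0 lower (18 and 0 adjusted over the list alone), with Psmb4 at 4.74 ± 0.76 (0.000339). The proteasome median was 1.64 (1.15 with bounds, 2.13 with a chip block, 1.93 within chip 6; adjusted p = 5.71e-06). DNA replication genes had 17 of 38 higher and 1 lower (20 and 2 adjusted over the list alone), with Mcm5 at least 5.77-fold higher (1.13e-05). The DNA replication median was 1.47 (0.52 with bounds, 1.67 with a chip block, 1.45 within chip 6; adjusted p = 0.000257). Ribosomal protein genes had 33 of 54 higher and 0 lower (38 and 0 adjusted over the list alone). The ribosomal protein median was 2.13 (1.92 with bounds, 1.86 with a chip block, 2.19 within chip 6; adjusted p = 1.94e-09, adjusted p = 0.0704 with an estimated correlation). Oxidative phosphorylation genes had 30 of 64 higher and 1 lower (39 and 1 adjusted over the list alone). The oxidative phosphorylation median was 1.61 (0.45 with bounds, 1.51 with a chip block, 1.93 within chip 6; adjusted p = 5.74e-06, adjusted p = 0.247 with an estimated correlation). Splicing genes had 17 of 38 higher and 2 lower (18 and 2 adjusted over the list alone). The splicing median was 1.52 (0.98 with bounds, 1.66 with a chip block, 2.25 within chip 6; adjusted p = 0.000752, adjusted p = 0.0559 with an estimated correlation). M phase genes had 12 of 29 higher and 1 lower (14 and 2 adjusted over the list alone). The M phase median was 1.19 (0.48 with bounds, 1.28 with a chip block, 1.54 within chip 6; adjusted p = 0.000752, adjusted p = 0.113 with an estimated correlation). Oocyte genes had 2 of 40 higher and 13 lower (2 and 13 adjusted over the list alone). The oocyte median was -0.92 (-0.92 with bounds, -0.79 with a chip block, -0.33 within chip 6, -0.18 with median scaling; adjusted p = 0.000266, adjusted p = 0.131 with an estimated correlation). 2-cell genes had 8 of 13 higher and 0 lower (8 and 0 adjusted over the list alone). The 2-cell median was 2.11 (0.57 with bounds, 1.48 with a chip block, 1.81 within chip 6; adjusted p = 0.000965, adjusted p = 0.0704 with an estimated correlation).

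limma called 2618 genes between drug controls and genomeless embryos, 1644 higher and 974 lower, and 3350 with a chip block. Without drug control B and C the count was 1640. The share higher was 62.8%, but 87.5% with median scaling and 49.3% (1502 higher, 1542 lower) without the 2 dim arrays. For activated genes the median was 2.41 with the block and 2.53 within chip 6, the only chip shared, and for lost genes -0.50 and -0.23 (-0.25 with median scaling, -1.04 to -0.19 on leaving out a sample).

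A genome transferred at M phase brought the 2-cell transcripts back. In M phase transfer embryos (n = 4) Dppa4 was at least 34.1-fold (adjusted p = 1.32e-06) and Alppl2 at least 13.9-fold (6.47e-09) higher than in genomeless embryos (n = 2). So were the cyclin-binding gene Zc3hc1, at least 25.9-fold (1.08e-06), the transcription elongation gene Supt4a at least 19.4-fold (1.46e-06) and the RNA polymerase I gene Znrd1 at least 18.1-fold (1.66e-07). Cd63 rose by 6.05 ± 0.91 (0.00017), Rps9 by 5.35 ± 0.56 (8.04e-06), Rps3 by 5.08 ± 0.59 (2.12e-05) and the ATP synthase gene Atp5g1 by 4.74 ± 0.40 (1.32e-06). Ccne1 was at least 11.6-fold (1.65e-05), Pramel7 at least 5.81-fold (9.77e-08), Klf2 at least 3.28-fold (1.79e-06), Nanog at least 1.63-fold (0.000622), Klf4 at least 1.57-fold (0.00405) and Eif1a at least 1.11-fold (0.00338) higher, while Pou5f1 (-0.93 ± 0.66, 0.302) and Smarca4 (0.53 ± 0.56, 0.504) were not called. Lower in the transfer embryos were Cnot6l, a deadenylase gene (-4.39 ± 0.44, 5.66e-06), Bmp15 (-3.73 ± 0.41, 1.19e-05), Btg4, an adaptor for maternal RNA decay (-2.99 ± 0.66, 0.00282), and Obox5 (-3.02 ± 0.50, 0.000389). Mdm4 (-4.65 ± 0.49, 9.3e-06), Tshz1 (-4.57 ± 0.87, 0.00105), Rims1 (-4.42 ± 0.51, 2.02e-05) and Gnpda2 (-4.41 ± 0.46, 8.36e-06) fell most. Of the activated genes 861 were higher and 9 lower (median 2.16, 1.05 with bounds, 1.31e-60; 2.16 with a chip block and 2.04 and 2.27 within chips 5 and 6). Of the lost genes 37 were higher and 355 lower (median -0.57, -0.39 with bounds, 4.56e-14; -0.57 with the block, -0.94 and -0.15 within chips, -0.19 with median scaling and -0.97 to -0.13 on leaving out a sample).

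Growth, oocyte and 2-cell lists all differed between M phase transfer and genomeless embryos. Ribosome biogenesis genes had 28 of 36 higher and 0 lower (30 and 0 adjusted over the list alone), with Ebna1bp2 (5.68 ± 0.47, 1.2e-06) and Nip7 (4.88 ± 0.70, 0.000119). The ribosome biogenesis median was 2.44 (1.69 with bounds, 2.44 with a chip block, 2.33 and 2.66 within chips 5 and 6; adjusted p = 2.94e-11). Proteasome genes had 16 of 31 higher and 0 lower (16 and 0 adjusted over the list alone), with Psmb4 (4.69 ± 0.66, 9.52e-05) and Psmb1 (4.17 ± 0.42, 5.77e-06). The proteasome median was 1.3 (1.1 with bounds, 1.3 with a chip block, 1.74 and 1.58 within chips 5 and 6; adjusted p = 2.1e-06). DNA replication genes had 17 of 38 higher and 1 lower (20 and 1 adjusted over the list alone), with Mcm5 at least 5.8-fold higher (2.44e-06). The DNA replication median was 1.25 (0.54 with bounds, 1.25 with a chip block, 1.2 and 1.58 within chips 5 and 6; adjusted p = 0.000184). Ribosomal protein genes had 34 of 54 higher and 0 lower (36 and 0 adjusted over the list alone). The ribosomal protein median was 1.92 (1.7 with bounds, 1.92 with a chip block, 2.32 and 1.87 within chips 5 and 6; adjusted p = 1.25e-08, adjusted p = 0.0905 with an estimated correlation). Oxidative phosphorylation genes had 38 of 64 higher and 2 lower (44 and 3 adjusted over the list alone). The oxidative phosphorylation median was 1.76 (0.8 with bounds, 1.76 with a chip block, 1.39 and 2.1 within chips 5 and 6; adjusted p = 2.27e-07, adjusted p = 0.179 with an estimated correlation). Splicing genes had 19 of 38 higher and 1 lower (19 and 1 adjusted over the list alone), with Snrpd2 at 4.84 ± 0.70 (0.000125). The splicing median was 1.57 (1.07 with bounds, 1.57 with a chip block, 1.21 and 2.14 within chips 5 and 6; adjusted p = 0.000732, adjusted p = 0.0525 with an estimated correlation). M phase genes had 11 of 29 higher and 3 lower (12 and 3 adjusted over the list alone), with Aurka at least 5.1-fold higher (2.66e-07). The M phase median was 1.13 (0.03 with bounds, 1.13 with a chip block, 0.48 and 1.11 within chips 5 and 6; adjusted p = 0.00872, adjusted p = 0.179 with an estimated correlation). Oocyte genes had 2 of 40 higher and 16 lower (2 and 17 adjusted over the list alone). The oocyte median was -0.94 (-0.94 with bounds, -0.94 with a chip block, -1.56 and -0.6 within chips 5 and 6, -0.47 with median scaling; adjusted p = 1.45e-05, adjusted p = 0.0905 with an estimated correlation). 2-cell genes had 7 of 13 higher and 0 lower (7 and 0 adjusted over the list alone). The 2-cell median was 1.43 (0.15 with bounds, 1.43 with a chip block, 1.42 and 1.31 within chips 5 and 6; adjusted p = 0.00872, adjusted p = 0.135 with an estimated correlation). The pluripotency list as a whole was not called (8 genes higher and 2 lower, 8 and 2 adjusted over the list alone, median 0.13, 0.286).

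limma called 2921 genes between M phase transfer and genomeless embryos, 1744 higher and 1177 lower (3566 with the block). The share higher was 59.7%, against 85.5% with median scaling and 70.9% in the mean-scaled values, where the median of all genes moved from 0.07 to 0.22, and 47.5% (1483 higher, 1639 lower) without the 2 dim arrays.

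Transfer at interphase gave few calls against having no genome at all. Interphase transfer embryos (n = 2) had more of the ribonuclease P subunit Rpp25 (at least 5.1-fold, adjusted p = 0.042) than genomeless embryos (n = 2). They also had more of Rabac1 (3.79 ± 0.77, 0.0361), the sulfotransferase gene Sult2a2 (3.52 ± 0.57, 0.0133) and Olig1 (at least 2.67-fold, 0.00855). Less was found of Leprotl1 (-3.99 ± 0.52, 0.004), the endosomal adaptor Appl1 (-3.60 ± 0.60, 0.0136), Qrfprl (-3.42 ± 0.45, 0.004), Gpr63 (-3.35 ± 0.60, 0.02) and the centriole gene Cep120 (at least 3.99-fold, 0.0209).

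Few activated genes were called between interphase transfer and genomeless embryos, where most lay at background. Of the activated genes 7 were higher and 5 lower (median 0.01, 0 with bounds, list adjusted p = 0.837; 0.01 with a chip block, 0 and 0.01 within chips 5 and 6), but 566 of the 1127 were detected in neither group and 229 more had only a bound, so this median mostly compares values near background. Nanog, Klf4, Eif1a and Smarca4 were not called (adjusted p = 1 for each), nor was Pou5f1 (0.949). Lost genes stood slightly higher, with 21 called higher and 6 lower (median 0.18, 0 with bounds, 0.0119, adjusted p = 0.362 with an estimated correlation; 0.18 with the block, 0.15 and 0.08 within chips). Their median was -0.05 without interphase transfer A. Ribosomal protein genes had 1 of 54 higher and 0 lower (1 and 0 adjusted over the list alone). The ribosomal protein median was 0.54 (0.16 with bounds, 0.54 with a chip block, 0.19 and 0.83 within chips 5 and 6; adjusted p = 0.000377, adjusted p = 0.474 with an estimated correlation). Oxidative phosphorylation genes had 1 of 64 higher and 0 lower (5 and 1 adjusted over the list alone), that of Ndufa1 (3.24 ± 0.71, 0.0499). The oxidative phosphorylation median was 0.49 (0 with bounds, 0.49 with a chip block, 0.19 and 0.86 within chips 5 and 6; adjusted p = 0.00118, adjusted p = 0.625 with an estimated correlation). DNA replication genes had 1 of 38 higher and 0 lower (2 and 0 adjusted over the list alone), that of Mcm5 (at least 1.83-fold, 0.0133). The DNA replication median was 0.41 (0 with bounds, 0.41 with a chip block, 0.34 and 0.21 within chips 5 and 6; adjusted p = 0.0418, adjusted p = 0.379 with an estimated correlation).

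limma called 78 genes, 49 higher and 29 lower (153 with the chip block, 25 with a replicate block). Without the 2 dim arrays 88 were called, of which only 12 were among the 78, and the share higher was 40.9%. Rpp25, Rabac1, Sult2a2, Olig1, Appl1, Gpr63, Cep120, Ndufa1, Mcm5, Psmb3 and Psmd4 lost their call there, and Leprotl1 and Qrfprl kept it. That fit leaves a single sample in each group and takes its spread from other groups, so a call kept or lost there is no firm check. The count was 936 without genomeless A and 753 without interphase transfer A. In simulated data 171 false calls arose with the unequal spread of these groups, more than the count itself. Among the 78 are the proteasome genes Psmb3 (3.69 ± 0.74, 0.0344) and Psmd4 (1.86 ± 0.36, 0.0262). The share higher was 62.8%, 85.7% with median scaling and 76.3% in the mean-scaled values.

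Compared directly, the embryos of M phase and interphase recipients differed in most of the 1127 activated genes. M phase transfer embryos (n = 4 against 2) had far more Mtres1, a mitochondrial RNA-binding gene (6.46 ± 0.32, adjusted p = 3.56e-08), Guca1a (5.84 ± 0.54, 3.09e-06), Dppa4 (5.69 ± 0.55, 5.08e-06) and Ccne1 (4.48 ± 0.56, 4.78e-05). Mfsd5 was at least 27.5-fold (7.18e-07), Ppp2cb at least 23.6-fold (1.21e-07), Timd2 at least 22-fold (3.39e-06) and Alppl2 at least 20.1-fold (7.46e-09) higher. The pluripotency regulators Klf5 (at least 6.33-fold, 1.21e-05), Klf2 (at least 4.74-fold, 1.44e-06), Nanog (at least 2.36-fold, 0.00193) and Klf4 (1.84 ± 0.41, 0.00408) were higher, as were Pramel7 (at least 8.41-fold, 6.8e-08), Eif1a (at least 1.61-fold, 0.0116) and the histone deacetylase gene Hdac1 (at least 5.51-fold, 4.89e-06). The pluripotency list as a whole was not called (median -0.01). Sox2 was 1.87-fold lower with M phase transfer embryos at their floor (0.0222). This is no strict bound, as Sox2 was detected on only 1 of the 2 interphase transfer arrays. Its call was lost without interphase transfer B, the dim array. The calls of Klf4, Eif1a and Btg4 were also lost without the dim arrays, and Pou5f1 (-0.32 ± 0.66, 0.748) and Smarca4 (0.63 ± 0.56, 0.425) were not called. Higher in interphase transfer embryos were Sult2a2 (at least 14.3-fold lower after M phase transfer, 1.55e-05), Cnot6l (-4.32 ± 0.44, 7.34e-06), Fndc3a (-4.29 ± 0.67, 0.000273), the bicarbonate transporter gene Slc4a8 (-4.20 ± 0.79, 0.00115), Defb48 (-4.13 ± 0.31, 6.19e-07), Bmp15 (-3.49 ± 0.41, 2.46e-05), the maternal-effect gene Ooep (-3.23 ± 0.44, 8.85e-05) and Btg4 (-2.78 ± 0.66, 0.00543). Of the activated genes 840 were higher and 8 lower (median 2.07, 1.43 with bounds, 1.29e-71; 2.07 with a chip block, 2.07 within chip 5 and 2.07 within chip 6). The block cannot change a median here, as both groups were split evenly over chips 5 and 6. Of the lost genes 7 were higher and 417 lower (median -0.91, -0.78 with bounds, 1.9e-23; -0.91 with the block, -1.16 and -0.60 within chips, -0.5 with median scaling and -1.17 to -0.57 on leaving out a sample). The plot of list medians shows these lists sample by sample.

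**Figure D3:**
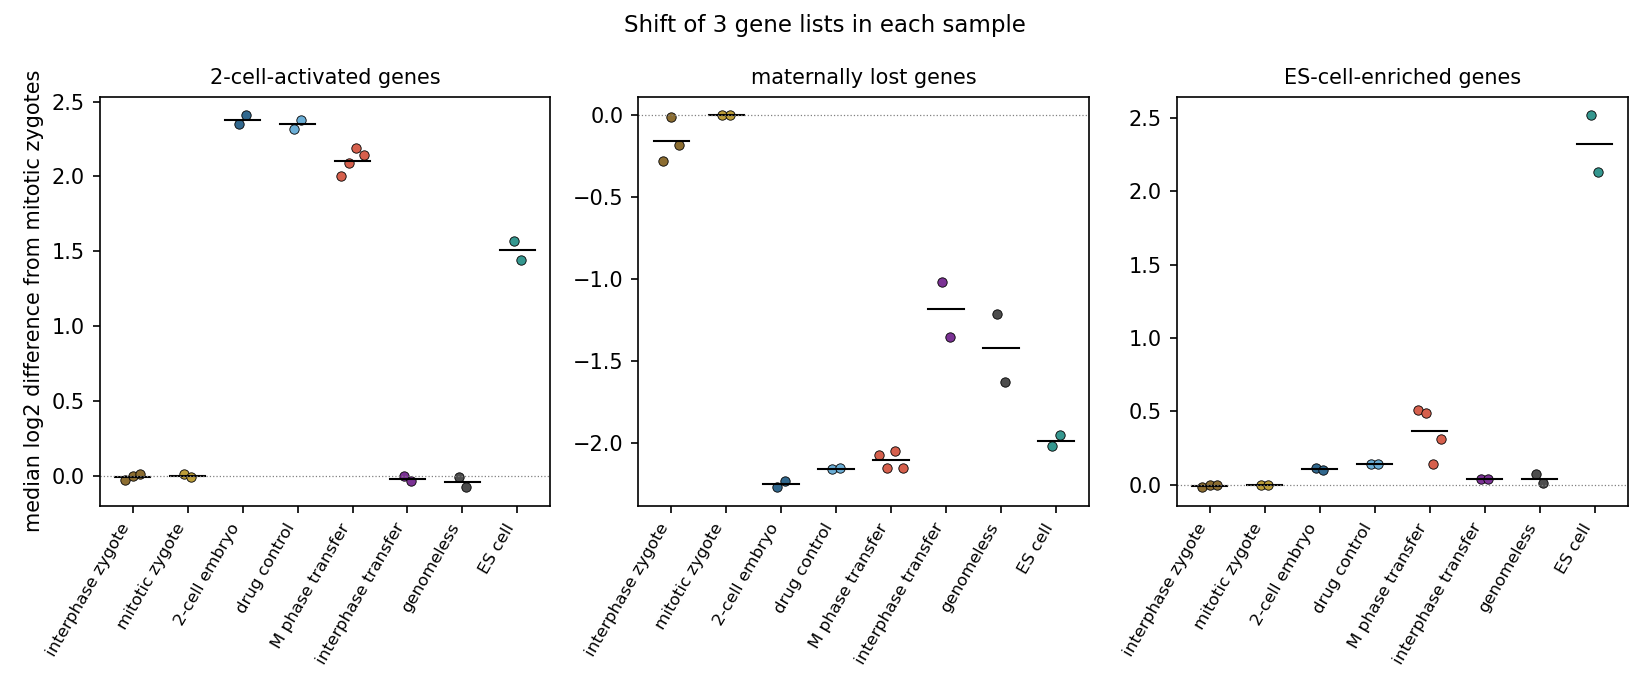
Median log2 difference from the mean of the mitotic zygotes (vertical axis) over the 2-cell-activated, maternally lost and ES-cell-enriched genes, with points as samples and lines as group means. For activated genes the M phase transfer samples lie between 2.00 and 2.19 and the interphase transfer group mean is -0.02.

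Growth and oocyte lists again divided the embryos. Ribosome biogenesis genes had 26 of 36 higher and 0 lower (32 and 0 adjusted over the list alone), including Nip7 (4.71 ± 0.70, 0.000191) and Rrp12 (at least 9.14-fold, 1.44e-06). The ribosome biogenesis median was 2.07 (1.84 with bounds, 2.07 with a chip block, 2.13 and 1.97 within chips 5 and 6; adjusted p = 2.92e-11). Proteasome genes had 15 of 31 higher and 0 lower (16 and 0 adjusted over the list alone), including Psmd13 (4.79 ± 0.85, 0.000743) and Psmb4 (4.70 ± 0.66, 0.000113). The proteasome median was 1.32 (0.81 with bounds, 1.32 with a chip block, 1.59 and 1.13 within chips 5 and 6; adjusted p = 1.34e-05). Ribosomal protein genes had 20 of 54 higher and 0 lower (22 and 0 adjusted over the list alone), including Rps9 (4.39 ± 0.56, 5.07e-05). The ribosomal protein median was 1.23 (1.23 with bounds, 1.23 with a chip block, 1.85 and 0.9 within chips 5 and 6; adjusted p = 1.26e-05, adjusted p = 0.21 with an estimated correlation). Oxidative phosphorylation genes had 25 of 64 higher and 2 lower (25 and 2 adjusted over the list alone), including Ndufs8 (at least 5.81-fold, 1.93e-05). The oxidative phosphorylation median was 0.92 (0.66 with bounds, 0.92 with a chip block, 0.99 and 0.93 within chips 5 and 6; adjusted p = 0.000286, adjusted p = 0.363 with an estimated correlation). DNA replication genes had 13 of 38 higher and 2 lower (17 and 2 adjusted over the list alone). The DNA replication median was 0.86 (0.68 with bounds, 0.86 with a chip block, 0.81 and 1.08 within chips 5 and 6; adjusted p = 0.00976, adjusted p = 0.131 with an estimated correlation). Splicing genes had 11 of 38 higher and 1 lower (14 and 1 adjusted over the list alone). The splicing median was 0.89 (0.61 with bounds, 0.89 with a chip block, 1.22 and 0.82 within chips 5 and 6; adjusted p = 0.0166, adjusted p = 0.161 with an estimated correlation). M phase genes had 11 of 29 higher and 1 lower (11 and 1 adjusted over the list alone). The M phase median was 0.61 (0 with bounds, 0.61 with a chip block, 0.54 and 0.96 within chips 5 and 6; adjusted p = 0.0208, adjusted p = 0.29 with an estimated correlation). Oocyte genes had 1 of 40 higher and 17 lower (1 and 19 adjusted over the list alone). The oocyte median was -1.08 (-1.08 with bounds, -1.08 with a chip block, -1.72 and -0.95 within chips 5 and 6, -0.57 with median scaling; adjusted p = 2.36e-06, adjusted p = 0.108 with an estimated correlation). 2-cell genes had 4 of 13 higher and 0 lower (4 and 0 adjusted over the list alone). The 2-cell median was 0.62 (0.37 with bounds, 0.62 with a chip block, 0.9 and 0.48 within chips 5 and 6; adjusted p = 0.0436, adjusted p = 0.288 with an estimated correlation).

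limma called 2484 genes between M phase and interphase transfer embryos, 1516 higher and 968 lower (3209 with the block). In simulated data 65% of genes changed by a log2 of 2 were recovered, with 118 false calls. The share higher was 61%, but 78% with median scaling and 46.4% (1340 higher, 1551 lower) without the 2 dim arrays.

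M phase transfer embryos came close to drug controls but not to identity. Against drug controls (n = 4 against 2) the glycolytic gene Gapdh was 2.50 ± 0.32 higher (adjusted p = 0.0074), Atpsckmt 2.46 ± 0.43 (0.0296), the RNA demethylase gene Fto 2.45 ± 0.43 (0.0304). Also higher were the DNA repair gene Babam2, at least 4.38-fold (0.0173), Iqcf5 1.86 ± 0.34 (0.0372) and the embryonic growth factor Fgf4 at least 1.94-fold (0.0273). Lower were the transcription factor gene Sox21 (-3.60 ± 0.52, 0.0137), Ramp2 (-2.64 ± 0.34, 0.0074), Allc (-2.03 ± 0.36, 0.0296), the endoderm factor Gata6 (-1.90 ± 0.35, 0.0372), Krt28 (-1.74 ± 0.24, 0.0112), complement C2 (-1.69 ± 0.26, 0.0176) and Pramel7 (-1.37 ± 0.25, 0.0372). Nop2 (-1.27 ± 0.26, 0.07), Hspb1 (2.00 ± 0.41, 0.07), Nanog, Pou5f1 and Smarca4 (adjusted p = 1 for each), Klf4 (0.573) and Eif1a (0.832) were not called. The activated genes stood slightly lower, with 1 called higher and 9 lower (median -0.26, -0.25 with bounds, 5.5e-10; -0.24 with a chip block, -0.19 within chip 6, the shared chip). Lost genes were not called as a list (2 and 0; median 0.03, 0 with bounds, 0.21; -0.05 with the block, 0.08 within chip 6). Ribosome biogenesis was lower as a list (0 and 0, 0 and 3 adjusted over the list alone; median -0.43, -0.43 with bounds, 5.91e-06, adjusted p = 0.0976 with an estimated correlation; -0.63 with the block, -0.4 within chip 6). So was the 2-cell list (0 and 1, 0 and 3 adjusted over the list alone; median -0.19, -0.19 with bounds, 0.0366, adjusted p = 0.48 with an estimated correlation; -0.46 with the block, which ended the call at 0.514, -0.15 within chip 6). Oxidative phosphorylation was called only with the block (0.11, 0.39 without it; 0.28, 0.00682 with it; -0.03 within chip 6). limma called 22 genes, 11 higher and 11 lower (20 with the block, 8 and 12). Of the 22, 12 were kept with the block, and Iqcf5, Fgf4, Allc, Gata6 and Pramel7 were not. The count was 0 without drug control B and C, 4 without drug control A, 12 and 8 without M phase transfer A and B and 56 without M phase transfer C. Of genes changed by a log2 of 2 in simulated data, 50% were recovered.

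Interphase transfer embryos had far less of many 2-cell transcripts than drug controls (n = 2 against 2). Timd2 was at least 50.1-fold (adjusted p = 2.98e-06), Ppp2cb at least 38.7-fold (2.6e-07), the protease gene Ctsb at least 31.8-fold (2.98e-06), Alppl2 at least 31.1-fold (1.3e-08) and Pramel7 at least 21.7-fold (3.21e-08) lower. Mtres1 (-6.30 ± 0.37, 1.58e-07), Guca1a (-6.07 ± 0.62, 9.26e-06) and Dppa4 (-5.72 ± 0.64, 2.19e-05) were lower, with Klf5 (at least 15.9-fold, 3.6e-06), Nanog (at least 2.18-fold, 0.00755) and Eif1a (at least 2.55-fold, 0.00346), while Klf4 (0.206), Pou5f1 (0.727) and Smarca4 (0.165) were not called. Higher were Caln1 (4.74 ± 0.65, 0.000121), Ss18l1 (4.71 ± 0.64, 0.000108), Fndc3a (at least 18.7-fold, 0.000514), the gamma-secretase gene Psenen (4.43 ± 1.05, 0.00635), Bmp15 (3.84 ± 0.47, 4.64e-05) and Cpeb1 (3.42 ± 0.54, 0.000399).

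All lists of growth genes were lower after interphase transfer than in drug controls, and oocyte genes were higher. Ribosome biogenesis genes had 0 of 36 higher and 29 lower (0 and 33 adjusted over the list alone), with Polr1e at least 14.3-fold lower (5.73e-06). The ribosome biogenesis median was -2.6 (-2.24 with bounds, -2.8 with a chip block, -2.45 within chip 6; adjusted p = 5.61e-14). Proteasome genes had 0 of 31 higher and 14 lower (0 and 15 adjusted over the list alone), with Psmb4 at -4.75 ± 0.76 (0.000405). The proteasome median was -0.93 (-0.82 with bounds, -1.51 with a chip block, -1.21 within chip 6; adjusted p = 4.61e-05). Ribosomal protein genes had 0 of 54 higher and 21 lower (0 and 23 adjusted over the list alone). The ribosomal protein median was -1.72 (-1.45 with bounds, -1.18 with a chip block, -1.05 within chip 6; adjusted p = 2.71e-06, adjusted p = 0.119 with an estimated correlation). Oxidative phosphorylation genes had 2 of 64 higher and 17 lower (3 and 19 adjusted over the list alone). The oxidative phosphorylation median was -0.88 (-0.68 with bounds, -0.77 with a chip block, -0.98 within chip 6; adjusted p = 0.00298, adjusted p = 0.506 with an estimated correlation). Splicing genes had 2 of 38 higher and 13 lower (2 and 14 adjusted over the list alone). The splicing median was -0.9 (-0.77 with bounds, -1.28 with a chip block, -1.06 within chip 6; adjusted p = 0.0124, adjusted p = 0.119 with an estimated correlation). DNA replication genes had 1 of 38 higher and 14 lower (3 and 14 adjusted over the list alone). The DNA replication median was -0.99 (-0.6 with bounds, -1.22 with a chip block, -1.03 within chip 6; adjusted p = 0.00893, adjusted p = 0.119 with an estimated correlation). M phase genes had 1 of 29 higher and 12 lower (1 and 12 adjusted over the list alone). The M phase median was -1.31 (-0.67 with bounds, -1.28 with a chip block, -1.22 within chip 6; adjusted p = 0.00203, adjusted p = 0.119 with an estimated correlation). Oocyte genes had 10 of 40 higher and 1 lower (10 and 1 adjusted over the list alone). The oocyte median was 0.98 (0.97 with bounds, 0.93 with a chip block, 0.93 within chip 6, 0.62 with median scaling; adjusted p = 4.61e-05, adjusted p = 0.119 with an estimated correlation). 2-cell genes had 0 of 13 higher and 6 lower (0 and 7 adjusted over the list alone). The 2-cell median was -1.63 (-0.5 with bounds, -1.52 with a chip block, -0.32 within chip 6; adjusted p = 0.00893, adjusted p = 0.119 with an estimated correlation). limma called 2267 genes, 811 higher and 1456 lower (2974 with the block). The count was 1314 without drug control B and C and 1441 without drug control A. The share higher was 35.8%, but 20.2% with median scaling and 51.6% (1487 higher, 1394 lower) without the 2 dim arrays.

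ES cells had more of the pluripotency list than 2-cell embryos and less of the oocyte and 2-cell lists. Against 2-cell embryos (n = 2 against 2) they had at least 65.2-fold more Wfdc2 (adjusted p = 6.35e-06), at least 59.9-fold more of the tetraspanin Cd81 (0.000456), 6.31 ± 0.62 more of the homeobox gene Rhox5 (1.42e-05), 5.78 ± 0.76 more of the RNA-binding gene Igf2bp1 (0.000206) and 5.44 ± 0.36 more Gapdh (8.13e-07). Gdf3 (4.64 ± 0.35, 1.95e-06), Tfcp2l1 (4.41 ± 0.70, 0.000816), Nanog (4.09 ± 0.58, 0.000366) and Eras (at least 11.5-fold, 1.76e-05) were higher and Pou5f1 was not called (2.02 ± 0.76, 0.0946), nor were Klf4 (0.918) and Sox2 (0.521). Missing or low in ES cells were Timd2 (at least 89.6-fold lower, 4.99e-06), the oocyte growth factor Gdf9 (at least 53-fold, 4.93e-07), Zscan5b (at least 52.9-fold, 2.88e-06), Oog1 (at least 48.5-fold, 3.23e-06), Alppl2 (at least 44.6-fold, 2.25e-08), Pramel7 (at least 39-fold, 3.8e-08) and Guca1a (-6.31 ± 0.62, 1.4e-05). Pluripotency genes had 14 higher and 1 lower (15 and 1 adjusted over the list alone; median 2.02, 2.02 with bounds, 6.74e-08). Oocyte genes had 0 and 17 (1 and 20 adjusted over the list alone; median -1.40, -0.97 with bounds, 8.13e-10) and the 2-cell list 1 and 8 (1 and 8 adjusted over the list alone; median -2.29, -1.66 with bounds, 7.62e-06). The fibroblast and feeder list, with Vim (4.69 ± 1.02, 0.00624), had 3 and 0 (6 and 0 adjusted over the list alone; median 2.51, 2.24 with bounds, 0.00247, adjusted p = 0.346 with an estimated correlation). Heat shock genes such as Hspb1 (3.97 ± 0.47, 8.19e-05) had 7 and 0 (7 and 0 adjusted over the list alone; median 0.78, 0.47 with bounds, 0.0016, adjusted p = 0.0511 with an estimated correlation), and oxidative phosphorylation 9 and 0 (8 and 0 adjusted over the list alone; median 0.68, 0.67 with bounds, 0.00281, adjusted p = 0.617 with an estimated correlation). ES cells and 2-cell embryos shared no chip, so no fixed chip term could be used, and a random block gave 1026 calls, 1025 of them among the 1311 (716 higher, 595 lower). The count was 639 without 2-cell B, 677 without 2-cell A and 839 without ES cell A.

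The label of ES cell A names peripheral blood as the source while its title names ES cells, and it detected most pluripotency genes and few blood cell genes. The tested Nanog probe measured 11.86 in sample A and 12.47 in sample B on the log2 scale, while the other 2 Nanog probes were not detected in sample A. Pou5f1 was weaker in sample A on both probes (7.15 and 7.55, against 8.75 and 10.05 in B), and 1 of 2 Sox2 probes was not detected there (6.59, against 8.14). Of 28 pluripotency genes on the array 24 were detected in sample A and 26 in sample B, and of 25 blood cell genes 4 in each. Ptprc, Hbb-bt, S100a8 and Lyz2 were not detected in sample A, but the T cell gene Cd3e was (7.53, and 6.75 in sample B). The blood cell list was not called against 2-cell embryos (2 genes higher and 0 lower, median 0.02, 0.517), although the haematopoietic membrane gene Laptm5 was at least 46.1-fold higher (0.00289) in both ES samples (11.99 and 12.22). Of 480 genes enriched at least 2-fold in ES cells over interphase zygotes, mitotic zygotes and 2-cell embryos alike, 98 were called higher and 9 lower in M phase transfer over genomeless embryos (median 0.28, 0 with bounds, 0.00848, adjusted p = 0.292 with an estimated correlation; 0.28 with a chip block, 0.35 and 0.24 within chips 5 and 6). Over interphase transfer embryos it was 90 and 19 (0.27, 0 with bounds, 0.00538, adjusted p = 0.282 with an estimated correlation; 0.27 with the block, 0.40 and 0.22 within chips), and over drug controls 5 and 0 (0.22, 0 with bounds, 8.87e-09; 0.17 with the block, 0.10 within chip 6). Interphase transfer over genomeless embryos gave a median of -0.01 (0.93), with 4 higher and 2 lower and 297 of the 480 detected in neither group, and drug controls over genomeless embryos 0.05 (0.837), with 62 and 16. Relative to mitotic zygotes the list stood at 0.36 (SD 0.17) in M phase transfer embryos, 0.14 in drug controls, 0.11 in 2-cell embryos and 2.33 (SD 0.28) in ES cells. The genes were chosen on the ES cell, zygote and 2-cell samples, so the gap between ES cells and 2-cell embryos is no separate evidence. Only the values of M phase transfer embryos and drug controls were left open by that choice.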

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

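All tests in this part were chosen after the results were seen. The effect of transfer against genomeless embryos differed between M phase and interphase recipients by 2.07 for 2-cell-activated genes, -0.91 for maternally lost genes and 0.27 for ES-cell-enriched genes (medians of the direct test). If the dim interphase transfer array B had made the gap in activated genes, leaving out the 2 dim arrays would have closed it, and the median was 2.13. If chip had made it, a within-chip value would have been small, and the lower was 2.07. Interphase transfer array A detected 82.4% of other genes of the same M phase transfer level and 38.9% of activated genes, B 56.7% and 22.3%. The excess (at least 34.4 points) leaves a low RNA yield open, as the other genes may include maternally lost ones, higher after interphase transfer. An earlier comparison of activated with maternally lost genes (62.9 and -4.3 points of detection lost, 67.2 apart) did not match levels and could not tell.

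The tests of the 584 genes measured higher in genomeless embryos than in mitotic zygotes were likewise chosen after the results were seen, with quantile normalisation added last. Whether the dim array genomeless B carries them could not be told, since their median went from 2.02 (SD 0.68) to 1.63 (SD 0.8) without it and 35.8% stayed called, with a single genomeless array left, against 64% without both dim arrays, where 878 genes were higher, and 1194 genes called from genomeless B alone had a median of 0.52 in A. New transcription from a retained genome could not be told from these genes, as 59.6% were higher in drug controls than in interphase zygotes, against 50% of all genes. The 1127 activated genes argue against a genome that was retained and transcribed as in 2-cell embryos. Their median over mitotic zygotes was -0.04 (SD 0.05) in genomeless embryos and 2.35 (SD 0.04) in drug controls. With bounds the difference between these groups was 1.25, and 22.9% and 98.3% of the activated genes were detected. Maternal RNA that is kept while the rest decays could explain the pattern, as 93% were higher in interphase transfer A than in interphase zygotes, although that sample shares a chip with genomeless A. Quantile normalisation of arrays with little signal could as well, since at most 49.1% stayed called with other scaling. The dim array, kept maternal RNA, quantile normalisation and RNA of adhering cumulus cells (3 tested genes, median 1.18, 0.27 with median scaling) remain open.

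M phase transfer samples on chip 5 and chip 6 differed from each other, with 216 genes apart between the pairs, 102 higher on chip 5 (Fam126b by 3.12, Slc38a2 by 3.03, Tipin by -2.94 and Med20 by -2.92). Whether a chip or amplification effect shared by all groups set these genes apart could not be told, as 54.6% of them had the same sign in genomeless embryos, against 58.4% of all genes, and 64.8% in interphase transfer embryos, against 61.9%. Over all genes part of the difference was shared. On the fourth component (8.9% of the variance) chip 5 samples of these groups lay between -63.6 and -24.5 and chip 6 samples between 9.3 and 40.6. Residuals of same-chip samples from different groups among them correlated at 0.06 to 0.46. Chip, amplification and RNA yield cannot be told apart here, as both dim arrays were on chip 6. A different degree of genome activation stays open, as the activated genes differed by -0.12 but the fixed 2-cell list by -0.72.

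Probes with no gene name were not analysed further. Of 1336 tested, 219 were called higher and 164 lower in 2-cell embryos than in mitotic zygotes.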

How the results depend on the processing

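Of the alternatives, 4 were added after the results were seen (21 separate arrays and neqc, both named in the design for the main fit, no dim arrays, array weights). Over comparisons and derived lists, 392 values stayed the same, 35 moved, 6 weakened and 1 strengthened, and of the leave-one-out values 103 stayed, 23 moved, 2 weakened and 1 reversed. Here a count of calls stayed the same if within a fixed ratio of the main count. A list or gene stayed the same if its call did not change, whatever its size. Within chips, where no test was run, a list did so if its median moved by less than the spread between samples. M phase transfer against drug controls (22) gave 35 without background correction, 43 with median scaling, 35 with the mean-scaled values, 41 without a filter, 10 with chip as a random block, 0 with groups fitted alone, 162 with 21 separate arrays, 68 without dim arrays and 1276 with weights. Interphase transfer against genomeless (78) gave 42 with median scaling, 153 and 129 with fixed and random chip, 25 with a replicate block, 51 with a trended robust fit, 0 alone, 209 separate and 0 with weights. Mitotic against interphase zygotes (0) gave 3 without a filter, 25 separate, 1 without dim arrays and 1273 with weights. Genomeless against mitotic (1738) gave 2667 with fixed chip. Fitted alone and with weights it gave 233 and 485, 2-cell against mitotic 4855 and 5117, drug control against genomeless 1025 and 1148, M phase transfer against genomeless 1824 and 1035 and against interphase transfer 1588 and 1036, and interphase transfer against drug controls 923 and 1181. The lost genes in interphase transfer over genomeless embryos weakened with an estimated correlation (0.18), with fry (0.18) and without dim arrays (0.15). ES-cell-enriched genes weakened with an estimated correlation in M phase transfer over genomeless (0.28) and interphase transfer (0.27) and with median scaling over genomeless (0.26), and strengthened in drug controls over genomeless without a filter (0.05). Fixed lists called numbered 60, and 15 with an estimated correlation, 69 with fry and 56 with fixed chip. The replicate block left 2350 calls for 2-cell against mitotic and 2165 for M phase against interphase transfer.

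Leaving out a sample gave 0 to 10 for mitotic against interphase zygotes, 1326 to 1452 for 2-cell against mitotic, 0 to 1 for drug control against 2-cell, 1640 to 3176 for drug control against genomeless, 625 to 2771 for genomeless against mitotic, 89 to 936 for interphase transfer against genomeless, 0 to 56 for M phase transfer and 1314 to 2431 for interphase transfer against drug controls and 639 to 1099 for ES cells. Lost genes in interphase transfer over genomeless embryos ranged from -0.05 (reversed, without interphase transfer A) to 0.39, and ES-cell-enriched genes in M phase over interphase transfer from 0.23 to 0.38. The cause of these shifts was not tested. Of the values of named genes, 3251 kept their call or lack of a call, 156 weakened and 26 strengthened, with 1077, 91 and 5 on leaving out a sample. No called value of a named gene changed sign, but uncalled ones did, such as Pou5f1 (-1.54 to 0.9) and Smarca4 (-0.69 to 1.96) in M phase over interphase transfer. The 2-cell-activated genes kept their direction but not their size: other settings gave 1.87 to 3.37 for M phase over interphase transfer and 1.93 to 3.58 over genomeless embryos, highest in the mean-scaled values.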

Other observations

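The genes and tests in this part were chosen after the results were seen. Some genes outside the growth lists rose with genome activation. Amhr2, the receptor for anti-Müllerian hormone, was at least 19.3-fold higher in 2-cell embryos than in mitotic zygotes (adjusted p = 3.76e-07), the trophectoderm regulator Tead4 at least 8.16-fold (8.99e-06) and the stress-induced pseudokinase gene Trib3 at least 9.18-fold (0.00152). Between M phase and interphase transfer embryos Trib3 was at least 5.59-fold higher (0.000128). The mitochondrial cell death gene Diablo rose by 2.28 ± 0.32 (0.00015) from mitotic zygote to 2-cell embryo and was 2.51 ± 0.28 higher in M phase than in interphase transfer embryos (1.54e-05), and the chaperone gene Hsph1 by 2.52 ± 0.40 (0.000413) and 1.58 ± 0.35 (0.00351, not called without interphase transfer A).

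The cell cycle inhibitor Cdkn1a, a p53 target, was 2.82 ± 0.80 higher in 2-cell embryos than in mitotic zygotes (0.0171), 3.24 ± 0.69 higher in M phase transfer than in genomeless embryos (0.00232) and 2.91 ± 0.69 higher than in interphase transfer embryos (0.00573), with no call against drug controls (0.58 ± 0.69, 1). The p53 list was not called in M phase over genomeless embryos (3 genes higher and 0 lower, 3 and 0 adjusted over the list alone, median 0.25, 0.803) or over interphase transfer embryos (5 and 1, 5 and 1 adjusted over the list alone, 0.04, 0.799), so no wider p53 response was measured. The first Cdkn1a call was lost without any 1 of the samples, without background correction and in the mean-scaled values, that over genomeless embryos without genomeless B and that over interphase transfer embryos without interphase transfer B. Dab2, an endocytic adaptor of the trophectoderm and endoderm, fell at the 2-cell stage (-1.91 ± 0.51, 0.0125, not called without either mitotic sample or 2-cell B) and was lower in M phase transfer than in genomeless embryos (-3.91 ± 0.44, 1.65e-05).

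The fibroblast and feeder list varied between single transfer samples. Relative to mitotic zygotes its median was 2.14 in M phase transfer D, 0.44 in A, 0.11 in B and -0.03 in C, and 0.84 in interphase transfer B and 0.02 in A, against 2.30 and 2.14 in the ES cell samples. Against drug controls the list was not called (0.64, 0.0545) but was called with chip as a block (1.1, 0.00638). The cause was not tested. Other lists with no call between 2-cell embryos and mitotic zygotes were apoptosis (0.88, 0.102), heat shock (0.05, 0.562), p53 (0.26, 0.562), primitive endoderm (0.88, 0.324), trophectoderm (-0.42, 0.706), pluripotency (0.23, 0.151), blood (0.33, 0.768) and fibroblast genes (0.17, 0.805), and the cumulus list had only 3 tested members.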
